A study of soil metagenome with 64 samples.

How the data were processed

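Soil DNA from 64 subplots of a grassland experiment was measured on 64 one-colour functional gene arrays. Per the labels' protocols, the Jasper Ridge Global Change Experiment divides circular plots into 4 quadrants. Nitrogen deposition and added water were applied to quadrants, and elevated CO2 and heat to whole plots. Per the same protocols, DNA was extracted by freeze-grinding, gel-purified, labelled with the dye Cy3 by random priming and hybridised to a GeoChip, an array of probes for microbial genes of known function. All arrays used here come from burned plots. Unburned plots are not analysed here, so no effect of fire is estimated.

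The deposited values are spot intensities on a linear scale, as the values themselves show. They are all above 0, and a blank stands where the authors did not keep a probe as detected. The most common step between neighbouring values of an array ranged from 0.05 to 0.36 between arrays. A factor per array applied before deposit could give this, but that was not tested. Whether such a factor was used, the scanner, the spot quantification, the detection threshold and the normalization are not described in the sources used here. The name of the deposited data holds the abbreviation SNR and the word rawdata, without an explanation of either. The table lists 68694 probes with a gene name, a functional category and, for most, an organism and its lineage. Of these, 3321 were detected on all 64 arrays and 2860 on none. No other columns of per-sample values were present (0 columns).

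Groups, replicate numbers and subplot numbers were read from the sample titles. The 16 groups are all combinations of nitrogen, water, heat and CO2, with 4 replicates each. A plot was taken as 4 consecutive subplot numbers, which gave 16 plots that each held all 4 nitrogen and water states. Each array was divided by a factor that brought its 75th percentile of log2 signal, over the 3321 probes detected on all arrays, to a common value. The factors ranged from 0.873 to 1.18. A gene family is a gene name as the deposited table gives it, matched without regard to case, which merged the spellings of 3 names. Its value is the log2 of the summed scaled signal of its probes, with undetected probes at 0. The 497 of 792 families above 0 on all 64 arrays were tested. Single probes were tested where detected on at least 75% of the arrays, which kept 20606, with undetected values left missing.

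Gene families and probes were tested with limma 3.58.1 in R 4.3.3, with lmFit, eBayes and Benjamini-Hochberg adjustment at 0.05. Nitrogen, water and their interactions were fitted within plots, with plot as a fixed block. Heat, CO2 and their interaction were fitted on the 16 plot means. A pairwise interaction is the difference between the effect of one treatment with and without the other. Intervals are 95% confidence intervals from the same fits. Shares of functional categories, kingdoms, phyla with at least 100 probes and 26 gene lists were taken as log2 of the share of total scaled signal. They were compared by exact two-sided tests, as were detected probes. For nitrogen and water the signs of the 16 within-plot differences were flipped in all 65536 ways. For heat and CO2 the plot means were reassigned within levels of the other factor in all 4900 ways. Community composition was compared on Bray-Curtis distances from vegan 2.7.1 by a permutational analysis of variance with 10000 permutations, within plots or between plots to match the treatment.

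The tests, the gene lists, the gene families to be named and most alternatives were fixed before the data were examined. The matching of list members to names with a taxon ending, and the leaving out of the names mdh and cat, which the table uses for other functions, were decided after the gene names were seen and before any test. Named families are 28 fixed in advance, of which 27 were measured under that name, and per treatment the 10 largest changes in each direction past the threshold. Each of the 27 is the entry of exactly that name, so entries of the same gene with a taxon ending are separate families. Where no family passed, the 5 with the smallest unadjusted p and at least 3 detected probes are given as values that did not pass.

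Replicate numbers were checked as pairs. Deviations from group means were correlated over families between same-numbered arrays with and without each treatment. The correlations ranged from 0.175 to 0.593 for nitrogen, 0.444 to 0.795 for water, 0.517 to 0.798 for heat and 0.571 to 0.746 for CO2. Every one was over 0.1, so the numbers were treated as pairing the samples, from the values and not from the labels. The tests, intervals and simulations for heat and CO2 follow the design fixed in advance, without the replicate number as a block, and the spread between numbers widens them. For heat and CO2 the median SE of a family change was 0.10 log2 without the block and 0.07 with it. No array duplicated another (0 identical pairs). Over the probes detected on all arrays, log2 signals correlated with a mean r of 0.623 within a group, 0.668 within a plot and 0.64 over all pairs of arrays, across probes.

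The fits were tested on simulated data made by reassigning treatments among real arrays and adding known changes to 60 of the 497 families. For nitrogen, 55.5% of changes of 0.25 log2, 96% of 0.5 and 100% of 1 were recovered at adjusted p 0.05. For water the shares were 56.5%, 95% and 100%, for heat 36%, 86.5% and 99.8%, and for CO2 32.5%, 85.8% and 99.5%. The adjustment is more lenient when many families change. These shares therefore hold for 60 changed families and would be lower if few families changed. Families with no added change were called on average 10.9 times per draw for nitrogen, 4 for water, 17.1 for heat and 0.75 for CO2, mostly in a few draws. Over the 20606 probes, 58% of nitrogen changes of 0.5 log2 and 22% of CO2 changes of that size were recovered. Alternatives tried were total-signal and quantile scaling, stricter and looser probe filters, mean log2 signal as the family value, other blocks, the number of detected probes as a covariate, other distances, and leaving out each replicate number. The number of arrays limits the precision. The labels do not say whether replicates were hybridised or extracted together. The p-values therefore judge differences only against the spread between these samples. That is the spread within plots for nitrogen, water and their interactions, and between plot means for heat, CO2 and their interaction.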

Results

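The arrays measured the abundance of microbial genes in soil DNA from burned plots of a California annual grassland under 4 simulated global changes. Nitrogen deposition, added water, heat and elevated CO2 were combined in all 16 ways, with 4 replicates per combination and 64 arrays in all. The burned plots with none of the 4 treatments were the ambient control. Because DNA was hybridised, the values describe gene abundance and not expression. An array detected between 13668 and 49354 of the 68694 probes, with a mean of 31668 ± 7996 (SD, n = 64). The ambient group averaged 26197 ± 11909 detected probes (SD, n = 4), and the group with heat and water, the highest, 37214 ± 2631 (SD, n = 4).

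**Figure D1:**
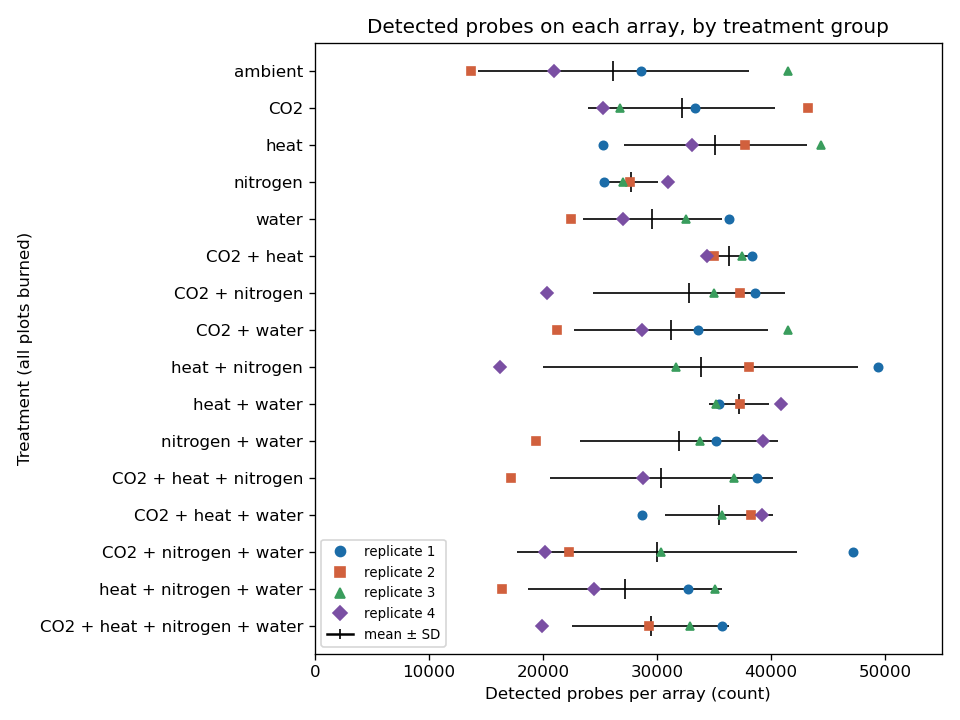
Number of detected probes (horizontal axis, count) on each of the 64 arrays, by treatment group (vertical axis). Points are arrays coloured by replicate number, and bars are the mean ± SD of 4 arrays. Arrays of one group spread widely, from 13668 to 41530 in the ambient group.

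A share of the signal depends on how many probes the array holds for a group as well as on gene abundance, so shares do not rank groups by abundance. Carbon cycling genes held 37.2% ± 1.41 of the signal (SD, n = 64) with 30.2% of the probes. Metal resistance genes held 14.6% ± 1.47 with 15.3% of the probes, organic remediation genes 10.9% ± 0.519 with 12.6%, nitrogen cycling genes 9.96% ± 0.690 with 8.42% and stress genes 7.60% ± 0.637 with 11.8%. Sulphur genes held 5.53% ± 0.251 and phosphorus genes 3.43% ± 0.533. By taxon, 89.5% ± 0.416 of the signal came from bacterial probes, 6.45% ± 0.446 from fungal, 2.81% ± 0.227 from archaeal and 0.365% ± 0.0421 from viral probes. Proteobacteria contributed 44.0% ± 1.06, Actinobacteria 18.9% ± 1.20, Firmicutes 7.25% ± 1.01 and the fungal phylum Ascomycota 4.94% ± 0.344. The actinobacterial alpha-amylase family amyA_Actinobacteria, of starch breakdown, held 3.63% ± 0.811 with 1383 probes. The exopolyphosphatase ppx held 2.34% ± 0.421, the bacterial and archaeal chitinase family 2.00% ± 0.383, the nitrate reductase gene narG 1.79% ± 0.158, the nitrogenase gene nifH 1.44% ± 0.200 and the ammonia monooxygenase gene amoA 1.24% ± 0.0819.

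Among the gene lists fixed in advance, starch degradation held 11.035% ± 1.60 of the signal (SD, n = 64), with 8.86% of the probes, the most of any list. Chitin degradation held 4.36% ± 0.631, pectin degradation 2.50% ± 0.120, hemicellulose degradation 2.44% ± 0.113, cellulose degradation 2.31% ± 0.257 and breakdown of lignin and aromatic carbon 2.30% ± 0.124. Carbon fixation held 4.35% ± 0.144 and methane cycling 0.378% ± 0.0309. In the nitrogen cycle, denitrification held 4.20% ± 0.382, ammonification and nitrogen assimilation 2.33% ± 0.207, nitrogen fixation 1.56% ± 0.220, nitrification 1.34% ± 0.0864, nitrate reduction by other routes 1.05% ± 0.117 and anaerobic ammonium oxidation 0.0171% ± 0.00548. Sulfur cycling held 5.40% ± 0.244, phosphorus cycling 3.45% ± 0.530, metal resistance 3.68% ± 0.237, aromatic remediation 2.61% ± 0.114 and antibiotic resistance 1.54% ± 0.0975. The stress lists were sigma factors with 1.82% ± 0.135, nutrient limitation with 1.71% ± 0.158, oxygen limitation with 1.09% ± 0.135, oxidative stress with 0.995% ± 0.0859, heat shock with 0.823% ± 0.0603, osmotic stress with 0.177% ± 0.0174 and cold shock with 0.0225% ± 0.00508.

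The first comparison asks how nitrogen deposition altered the gene pool of burned soil. No gene family passed the test, and most point estimates lay slightly below 0. Of the nitrogen cycling families, amoA differed by -0.06 log2 with nitrogen (95% interval -0.13 to 0.02), nifH by -0.09 (-0.22 to 0.05), narG by -0.04 (-0.14 to 0.05) and the nitrite reductase gene nirK by -0.05 (-0.15 to 0.04). The urease gene ureC differed by -0.05 (-0.13 to 0.04), the nitrous oxide reductase gene nosZ by -0.02 (-0.16 to 0.11) and hao, which encodes hydroxylamine oxidoreductase, by 0.04 (-0.13 to 0.20). Of the carbon degradation families, phenol_oxidase differed by -0.08 (-0.17 to 0.01), amyA by -0.05 (-0.13 to 0.03), cellobiase by -0.01 (-0.10 to 0.08) and endochitinase by -0.05 (-0.13 to 0.04). These are single entries of their genes. The entry amyA held 1.02% of the signal, against 3.63% for amyA_Actinobacteria, which it does not include. The methane monooxygenase gene pmoA differed by -0.10 (-0.22 to 0.02) and the catalase gene katA by -0.16 (-0.40 to 0.09).

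With limma, 0 of 497 families passed adjusted p 0.05 for nitrogen, and 15 had an unadjusted p under 0.05, all lower with nitrogen, where 24.9 are expected by chance. Adjusted over the list alone, 0 of the 27 families fixed in advance passed, with a lowest adjusted p of 0.486. Of the 27, 25 were lower and 2 higher, but under total-signal scaling 8 were lower and 19 higher. The smallest unadjusted limma p was that of cspB, a cold shock protein gene, at 15.97 ± 0.80 log2 with nitrogen and 16.37 ± 0.44 without (SD, n = 32). The cspB difference of -0.40 had an interval of -0.68 to -0.11, and the limma adjusted p was 0.533. It was higher with nitrogen in 5 of 16 plots. The next 4 were nepovirus polymerase probes (-0.37, interval -0.66 to -0.09), dmdA, for demethylation of dimethylsulfoniopropionate (-0.14, -0.26 to -0.02), por_DiC4HB (-0.20, -0.37 to -0.03) and the fungal nitrite reductase family nirK_fungi (-0.18, -0.35 to -0.02). The share of the cold shock list was 0.0210% ± 0.00529 with nitrogen and 0.0240% ± 0.00444 without (SD, n = 32), higher with nitrogen in 4 of 16 plots, with an exact permutation p of 0.0214 and an adjusted p of 0.557 over 26 lists. Of its 2 tested members, cspB passed when adjusted over the list alone, with a limma adjusted p of 0.0147. Without replicate 2 its difference was -0.20 with an unadjusted p of 0.0838, without replicate 4 it was -0.33 with 0.0716, and without the 6 arrays under 20000 detected probes, an alternative chosen after seeing the data, -0.26 with 0.0705. Without replicate 1 it was -0.57 with an unadjusted limma p of 0.0028, and without replicate 3 it was -0.48 with 0.0079. In every other list 0 members passed when adjusted over the list alone.

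At the level of lists and taxa, 0 of 26 lists, 0 of 16 categories, 0 of 6 kingdoms and 0 of 20 phyla passed for nitrogen by exact permutation, with 1 list and no other group at an unadjusted p under 0.05. All 7 denitrification and all 13 starch families had estimates below 0 without passing, but under total-signal scaling 6 of the 7 and 7 of the 13 lay above 0. The shares of these lists differed by 0.03 and -0.03 log2. Some other lists mostly kept their sign under total-signal scaling, with 16 of 18 metal resistance and all 4 sigma factor families below 0. Further lists turned. Pectin degradation went from 2 families above 0 and 13 below to 13 above and 2 below. Carbon fixation went from 0 above and 9 below to 8 above and 1 below, and sulfur cycling from 1 above and 16 below to 11 above and 6 below. Of all 497 families, 49 lay above 0, and 217 under total-signal scaling. For single probes, limma called 0 of 20606, and 396 had an unadjusted p under 0.05. Detected probes averaged 30422 ± 8576 with nitrogen and 32915 ± 7292 without (SD, n = 32), a difference with an exact permutation p of 0.265. The difference was 5414, -5168, -4070 and -6149 within replicate numbers 1 to 4, so replicate 1 had the opposite sign. The median change of all families was -0.08, against -0.01 with total-signal scaling and -0.14 with quantile scaling. Within replicate numbers 1 to 4 the median change was 0.07, -0.14, -0.05 and -0.18, and limma called 0 families in each. All 497 intervals lay within 1 log2 unit of 0, and 475 within 0.5.

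With added water, the families fixed in advance had estimates between -0.05 and 0.10 log2. The family amoA differed by 0.01 log2 (95% interval -0.06 to 0.09), nirS by -0.02 (-0.11 to 0.08), nosZ by -0.05 (-0.18 to 0.09) and ureC by -0.00068 (-0.08 to 0.08). Among carbon families, amyA differed by -0.01 (-0.09 to 0.07), endoglucanase by -0.01 (-0.10 to 0.07) and rubisco, for carbon fixation, by 0.02 (-0.10 to 0.14). The osmoprotectant transport gene proV differed by 0.09 (-0.07 to 0.25), and the share of the osmotic stress list was 0.180% ± 0.0146 with water and 0.173% ± 0.0194 without (SD, n = 32), higher in 10 of 16 plots, with an exact permutation p of 0.0881 and an adjusted p of 0.991. The 5 families with the smallest p were mannanase_fungi, of hemicellulose breakdown (-0.25, interval -0.44 to -0.05), nitrogen_fixation_genes (0.35, 0.06 to 0.63), ChnE, of cyclohexanol breakdown (-0.18, -0.34 to -0.03), the beta-xylosidase gene xlnD (-0.19, -0.37 to -0.02) and hmgC_fungi (-0.12, -0.23 to -0.01). None of these passed, with a limma adjusted p of 0.999 for each.

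For water limma called 0 of 497 families, with 9 at an unadjusted p under 0.05, and 0 of 20606 probes, with 597 at an unadjusted p under 0.05. Adjusted over the list alone, 0 of the 27 families passed, with 14 above and 13 below 0 and a lowest adjusted p of 0.965. By exact permutation 0 of 26 lists, 16 categories, 6 kingdoms and 20 phyla passed. The soil-borne pathogen category held 0.727% ± 0.0360 with water and 0.741% ± 0.0317 without (SD, n = 32), higher with water in 3 of 16 plots, with an exact permutation p of 0.0445 and an adjusted p of 0.711. Detected probes averaged 31512 ± 7537 with water and 31825 ± 8549 without (exact permutation p = 0.872), and the difference within replicate numbers 1 to 4 was 882, -5391, -431 and 3689. Within replicate numbers 1 to 4 the median family change was 0.03, -0.09, -0.03 and 0.07, and limma called 0 families in each. Of the 497 intervals, 485 lay within 0.5 log2 of 0.

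**Figure D2:**
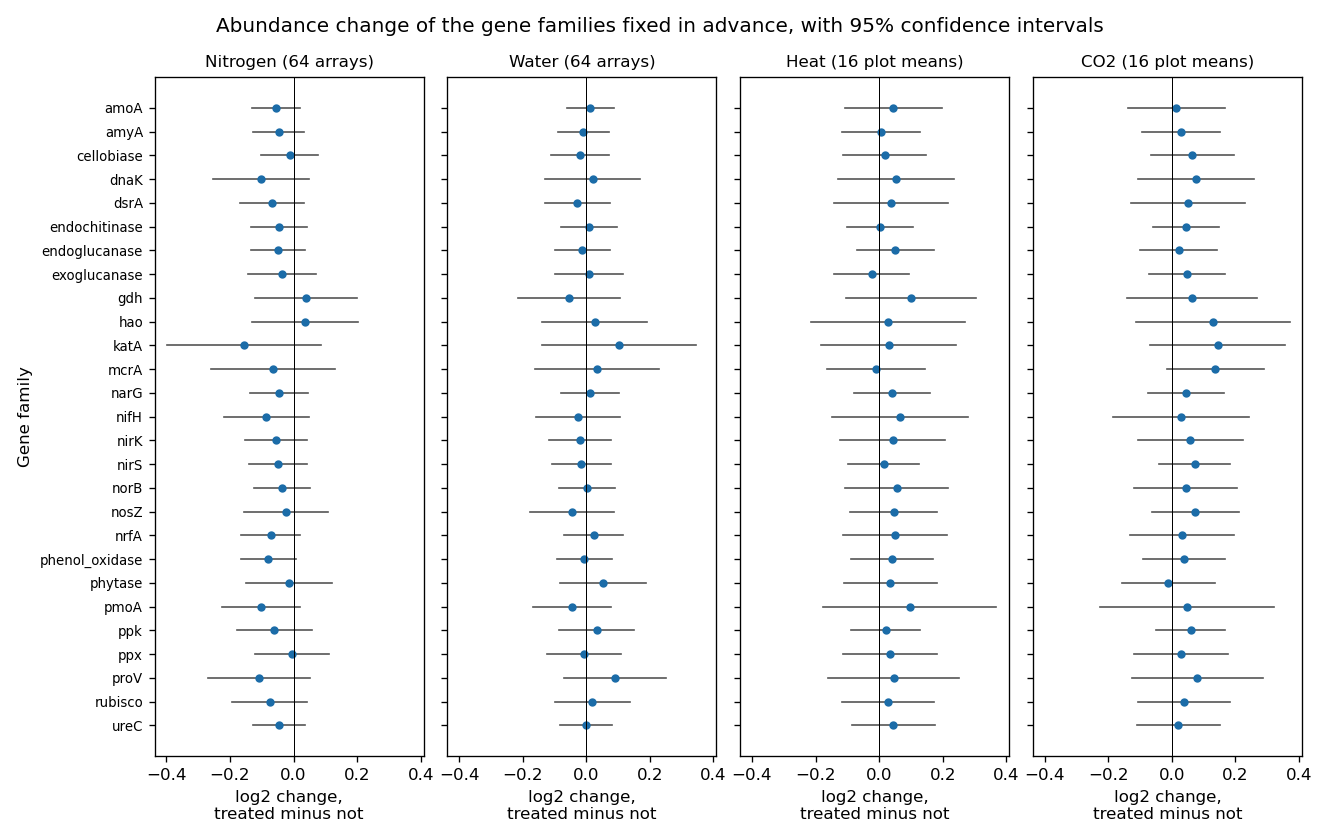
Change in abundance (horizontal axis, log2, treated minus not treated) of the 27 gene families fixed in advance (vertical axis), for nitrogen, water, heat and CO2. Points are limma estimates and bars 95% confidence intervals. No family passed the test in any panel, and estimates ranged from -0.16 to 0.14, with signs that depend on the scaling.

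Heat was compared between 8 heated and 8 unheated plots. The heat shock chaperone gene dnaK differed by 0.05 log2 (95% interval -0.13 to 0.24) and katA by 0.03 (-0.18 to 0.24). In the nitrogen cycle, gdh, for glutamate dehydrogenase, differed by 0.10 (-0.10 to 0.31), nifH by 0.07 (-0.15 to 0.28), norB by 0.06 (-0.11 to 0.22) and amoA by 0.05 (-0.11 to 0.20). In the carbon families, endoglucanase differed by 0.05 (-0.07 to 0.17), exoglucanase by -0.02 (-0.14 to 0.10), pmoA by 0.10 (-0.18 to 0.37) and the methanogenesis gene mcrA by -0.01 (-0.16 to 0.14). The smallest p values belonged to ChnE (0.21, interval 0.05 to 0.36), the pentachlorophenol pathway gene pcpA (0.35, 0.04 to 0.66) and scytalone_dehydratase_Fungi, of melanin synthesis (-0.14, -0.28 to -0.01). They were followed by the iron uptake gene fhuA (0.16, 0.0035 to 0.31) and the bacterioferritin gene bfr (0.19, -0.01 to 0.39). None passed, with a limma adjusted p of 0.970 for each.

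For heat limma called 0 of 497 families, with 5 at an unadjusted p under 0.05, and 0 of 20606 probes, with 461 at an unadjusted p under 0.05. Adjusted over the list alone, 0 of the 27 families passed, with a lowest adjusted p of 0.920. Of these, 25 lay above 0, against 12 under total-signal scaling. All 6 heat shock families and all 5 oxidative stress families lay above 0 without passing, against 5 and 3 under total-signal scaling. The shares of both lists differed by 0.01 log2, with exact permutation p of 0.754 and 0.704. No list, category, kingdom or phylum passed (0 of 26, 16, 6 and 20). Detected probes averaged 33121 ± 3112 in heated plots and 30215 ± 5613 in unheated plots (SD, n = 8, exact permutation p = 0.243). Within replicate numbers 1 to 4 the difference was 773, 5226, 2593 and 3032, above 0 in all 4, and with plots reassigned only within numbers the exact permutation p was 0.0941. The median change of all families was 0.04, with 395 of 497 above 0, against 0.14 and 482 under quantile scaling and 0.0044 and 259 under total-signal scaling, so the shift depends on the scaling. Within replicate numbers 1 to 4 it was -0.01, 0.11, 0.04 and 0.04, and limma called 0 families in each number, with 24, 10, 19 and 5 at an unadjusted p under 0.05. With 4 plots and 1 residual degree of freedom per number, few calls were possible, so these 0 carry little weight. Of the 497 intervals, 449 lay within 0.5 log2 of 0.

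Elevated CO2 was compared between 8 plots with and 8 without it. The methanogenesis gene mcrA differed by 0.14 log2 (95% interval -0.02 to 0.29), and the methane cycling list held 0.384% ± 0.00959 of the signal with CO2 and 0.372% ± 0.0127 without (SD, n = 8), with an exact permutation p of 0.0608 and an adjusted p of 0.943. Plant litter families lay near 0, with cellobiase at 0.06 (-0.07 to 0.19), exoglucanase at 0.05 (-0.07 to 0.17), phenol_oxidase at 0.04 (-0.09 to 0.17) and amyA at 0.03 (-0.09 to 0.15). In the nitrogen cycle, hao differed by 0.13 (-0.11 to 0.37), nirS by 0.07 (-0.04 to 0.18), nosZ by 0.07 (-0.06 to 0.21) and nifH by 0.03 (-0.19 to 0.24). The phosphorus families ppk, ppx and phytase differed by 0.06 (-0.05 to 0.17), 0.03 (-0.12 to 0.18) and -0.01 (-0.16 to 0.14). The smallest p values belonged to hrcU, of type III secretion (0.29, interval 0.06 to 0.52), the siderophore gene sidA (0.22, 0.04 to 0.40), NADH_quinone_oxidoreductase (0.23, 0.03 to 0.42), nicdehydr (0.27, 0.01 to 0.52) and lipase_fungi (0.42, 0.01 to 0.84). None passed, with a limma adjusted p of 0.989 for each.

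For CO2 limma called 0 of 497 families, with 5 at an unadjusted p under 0.05, and 0 of 20606 probes, with 340 at an unadjusted p under 0.05. Adjusted over the list alone, 0 of the 27 families passed, with a lowest adjusted p of 0.831. Of these, 26 lay above 0, against 19 under total-signal scaling. Of all 497 families, 393 lay above 0, against 286 under total-signal and 436 under quantile scaling. The metal resistance category held 14.3% ± 0.372 of the signal with CO2 and 14.8% ± 0.730 without (SD, n = 8, exact permutation p = 0.0690, adjusted p = 0.803). The narrower metal resistance list did not go the same way. All 18 of its tested families lay above 0, also under total-signal and quantile scaling, without passing. By exact permutation 0 of 26 lists, 16 categories, 6 kingdoms and 20 phyla passed. Detected probes averaged 32236 ± 4514 with CO2 and 31101 ± 4990 without (SD, n = 8, exact permutation p = 0.627). Within replicate numbers 1 to 4 the difference was 3248, 3888, -591 and -2003, and with plots reassigned only within numbers the exact permutation p was 0.560. Within replicate numbers 1 to 4 the median family change was 0.06, 0.14, 0.01 and -0.03. On the 4 plots of each number limma called 0 families, with 20, 14, 66 and 3 at an unadjusted p under 0.05, and 1 residual degree of freedom left little room for calls. Of the 497 intervals, 466 lay within 0.5 log2 of 0.

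Whether one treatment altered the effect of another was tested for the 6 pairs. Limma called 0 of 497 families and 0 of 20606 probes for each pair. Families at an unadjusted p under 0.05 numbered 81 for nitrogen with heat, all with a lower nitrogen effect under heat, 8 for nitrogen with water, 8 for nitrogen with CO2, 11 for water with heat, 5 for water with CO2 and 1 for heat with CO2. For nitrogen with heat the smallest p values, named after their values were seen, belonged to the nickel resistance gene nreB (-0.64 ± 0.20, SE), the fungal catalase family cat_fun (-0.54 ± 0.18, SE) and the carbonic anhydrase gene IcfA (-0.72 ± 0.24, SE). Each had a limma adjusted p of 0.288. The nitrogen effect on nreB was -0.31 in heated and 0.33 in unheated plots. The 81 became 17 with the number of detected probes as a covariate. With 1 replicate number left out, the count ranged from 13 without replicate 4 to 174 without replicate 1. It was 11 of 540 families without the 6 arrays under 20000 detected probes, an alternative chosen after seeing the data. As mean log2 signal of probes detected on every array it was 19 of 372, and over probes detected on at least 75% of arrays 25 of 468. Under total-signal scaling it was 53, and under quantile scaling 97. For nitrogen with CO2 the smallest p was that of hzo, of anaerobic ammonium oxidation (-0.65 ± 0.24, SE), and for water with heat the nitrite reductase gene nirB differed by 0.33 ± 0.13 (SE), with limma adjusted p of 0.994 and 0.997. Probes at an unadjusted p under 0.05 numbered 1221 for nitrogen with water, 1116 for nitrogen with heat, 450 for nitrogen with CO2, 1244 for water with heat, 470 for water with CO2 and 98 for heat with CO2. A share of 0.05 is expected by chance. Nitrogen with water (5.93%), nitrogen with heat (5.42%) and water with heat (6.04%) lay above it, and the other pairs below. As many came in 31, 32 and 27 of 100 assignments within plots, the real one among them.

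Community composition over all 68694 probes was compared by Bray-Curtis distance. Nitrogen accounted for 1.24% of the variation (permutation p = 0.575), water for 1.02% (p = 0.759 by permutation), heat for 1.42% (p = 0.709 by permutation) and CO2 for 1.35% (p = 0.752 by permutation). Among pairs of treatments the largest part was that of nitrogen with heat, at 2.27% (permutation p = 0.103), and the others ranged from 0.843% to 1.67%. The lowest adjusted p over the 10 effects was 0.896. These tests concern treatment effects within burned plots only, and they set no upper limit on an effect. A p that missed the threshold does not show that the communities were alike.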

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

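The diversity of signal was compared within each of the 16 groups as a Shannon index over probes, a measure chosen after the data were seen. In the group with CO2 and nitrogen, replicate 4 had an index of 9.72, while the other 3 arrays lay between 10.2 and 10.3. Its distance from them, relative to the range of the group, was beyond what 4 values give in about 1 of 20 groups by chance, and it was the 1 array marked in this way among 16 groups. The same array had 20366 detected probes, against 34987 to 38632 on the others, and for detected probes 0 of 16 groups held such an array. No explanation was tested for this array.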

How the results depend on the processing

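Counts of gene families and probes past adjusted p 0.05 in limma stayed at 0 for every treatment and pair, and counts of gene lists by exact permutation for every single treatment, under all alternatives run, including total-signal and quantile scaling, other probe filters, other blocks and leaving out each replicate number. With the replicate block the counts were also 0, so the block changed no call. Between plots the block raised the families at an unadjusted p under 0.05 from 5 to 21 for heat, from 5 to 16 for CO2 and from 1 to 10 for heat with CO2, and the probes from 461 to 1111, from 340 to 1671 and from 98 to 580. A share of 0.05 of the probes is expected by chance. The heat and CO2 probe counts lay above it with the block and below it without. The count for heat with CO2 lay below it in both. Community p by permutation moved with the block from 0.709 to 0.192 for heat and from 0.752 to 0.223 for CO2. Families at an unadjusted p under 0.05 ranged from 1 to 90 for nitrogen, 2 to 18 for water, 1 to 35 for heat, 0 to 27 for CO2 and 11 to 174 for nitrogen with heat. The exception among the community results was nitrogen with heat on Jaccard distances of detected probes, at 2.79% of the variation (permutation p = 0.0445), where the other alternatives gave p from 0.052 to 0.398; the cause was not tested. Of 128 named pairs of family and treatment, 0 of 1588 alternative values passed, and 86 pairs changed sign in at least 1 alternative. Leaving out the 6 arrays with under 20000 detected probes, and the replicate block with detected probes as a covariate, were chosen after seeing the data. The number of arrays and the detection threshold, which blanks weak signals, limit what could be seen.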

Other observations

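The reassignments of treatments, both tests for nitrogen with heat, and the tests of detected probes and of an array batch for replicate numbers, with the fit without 6 arrays and the group shares over probes detected on every array, were chosen only after the result was seen. Shares of taxa differed between the 4 replicate numbers, whose detected probes also differed. Actinobacteria held 18.3% ± 0.318, 19.4% ± 0.200, 17.9% ± 0.548 and 19.96% ± 0.162 of the signal in replicates 1 to 4 (SD, n = 4 plots each), with an exact permutation p of 0.000145 and an adjusted p of 0.00145 over 20 phyla. Firmicutes held 7.51% ± 0.246, 6.70% ± 0.135, 8.15% ± 0.485 and 6.63% ± 0.112 (adjusted exact permutation p = 0.00181). The fungal phylum Ascomycota held 4.83% ± 0.121, 5.29% ± 0.0762, 4.74% ± 0.138 and 4.91% ± 0.0799 (adjusted exact permutation p = 0.00245). In all, 16 of 20 phyla, 8 of 16 functional categories and 14 of 26 lists differed at adjusted p 0.05, while nitrogen, carbon, sulphur and phosphorus cycling categories did not pass. Some narrower lists of carbon and nitrogen functions did pass. They were lignin and aromatic carbon degradation and carbon fixation (adjusted exact permutation p = 0.0172 each), hemicellulose degradation, pectin degradation and anaerobic ammonium oxidation (0.0314 each) and nitrogen fixation (0.0498). Of those 8 categories, 6 had shares that followed the number of detected probes across arrays. Over the 3321 probes detected on every array, 10 of the 16 phyla, 3 of the 8 categories and 3 of the 14 lists still differed by the same exact permutation test, with Actinobacteria, Firmicutes and Ascomycota among the phyla (adjusted p = 0.0151, 0.00434 and 0.0151). Among the 10, Aquificae rested on 1 probe and Synergistetes on 3. Only 24 lists had values, without cold shock and anaerobic ammonium oxidation, both among the 14. The order of the numbers could change. Ascomycota now held 4.17%, 4.25%, 4.08% and 4.10%, and Cyanobacteria were lowest in replicate 1, against replicate 4 over all probes.

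By limma's F test on the 16 plot means, 243 of 497 gene families differed between replicate numbers at adjusted p 0.05, and 20.7% of the 497 did without the 6 arrays under 20000 detected probes. The families named here were chosen after their values were seen. The bacterial siderophore family sid_bac stood at 18.53 ± 0.17, 17.38 ± 0.39, 18.72 ± 0.10 and 17.76 ± 0.34 log2 in replicates 1 to 4 (SD over 4 plots, limma adjusted p = 0.000603). The atrazine pathway gene atzC stood at 18.86 ± 0.06, 18.23 ± 0.21, 18.94 ± 0.11 and 18.37 ± 0.12 (limma adjusted p = 0.000376). The elicitin family of oomycetes, plant pathogens, stood at 19.27 ± 0.10, 19.73 ± 0.10, 19.21 ± 0.16 and 19.53 ± 0.07 (limma adjusted p = 0.000832). Replicate numbers accounted for 17.7% of the Bray-Curtis variation (exact permutation p = 0.000145). Over the 3321 probes detected on every array they accounted for 15.4% (exact permutation p = 0.000145). In simulated data for this comparison over 497 families, 48.8% of shifts of 0.5 log2 in one replicate number were recovered.

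Chance is unlikely but not excluded for the difference between replicate numbers. Of 100 of the 13824 rearrangements of the numbers among plots of one CO2 and heat state, only 1, the real one, gave as many as 243 families. The highest other gave 193. Detected probes also differed, at 35175 ± 2822, 28526 ± 5245, 34858 ± 1543 and 28115 ± 3091 (SD, n = 4 plots each, exact permutation p = 0.0336). When only probes detected on every array were averaged, 32.3% of families (120 of 372) still differed. This does not show whether detected probes are the whole cause. Values over those probes can still follow the number of detected probes, as the stress share did (r = -0.483). With detected probes as a covariate the numbers dropped to 41 of 372 in that measure and to 25 of 497 in summed signal. Each replicate number holds 4 plots, and the labels give no array or extraction batch. A batch of arrays and a difference in place or fire history therefore cannot be told apart for the 17.7%; the labels mention an earlier wildfire in some blocks without linking it to these samples, so fire history was not tested.

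In heated plots the nitrogen effect was lower than in unheated plots in 81 families at an unadjusted p under 0.05, without one passing in limma after adjustment. The count was 174 without replicate 1, 28 without replicate 2, 73 without replicate 3 and 13 without replicate 4. Without the 6 arrays under 20000 detected probes, an alternative chosen after seeing the data, it was 11 of 540 families. Among those 6, the arrays with both heat and nitrogen had 16267, 16395, 17208 and 19943 detected probes. The others were an ambient array with 13668 and an unheated array with nitrogen and water with 19395. Chance was not excluded, since 7 of 100 assignments within plots, the real one among them, gave as many. The highest other gave 176. Detected probes differed by -5808 with nitrogen in heated plots and by 821 in unheated plots (exact permutation p = 0.134 for the difference). With detected probes as a covariate 17 families remained under 0.05, where 24.9 are expected by chance, and 16 of them were among the 81. The median of the 81 differences moved from -0.39 ± 0.16 to -0.18 ± 0.12 (SD over families) while their median SE fell from 0.17 to 0.12, so the count dropped because the differences shrank. The pattern may thus follow the number of detected probes, and an effect of the treatments on that number stays open.

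The shares of 13 of 16 functional categories followed the number of detected probes across the 64 arrays at adjusted p 0.05, 8 of them positively. The stress share had r = 0.916 and rho = 0.859 (permutation p = 0.00001 each, the smallest 100000 permutations can give; adjusted p = 0.00002), and r = 0.912 without the 2 arrays farthest from the median. Within replicates 1 to 4 its r was 0.828, 0.951, 0.778 and 0.962. The nitrogen cycling share had r = -0.565 and rho = -0.514 (permutation p = 0.00001 each), r = -0.506 without those 2 arrays, and r of -0.541, -0.715, -0.270 and -0.759 within replicates. The prediction, written before this test, was that with a detection threshold as the cause under 50% of these categories would keep the relation, with its sign, over probes detected on every array. Over those probes 0% of the 13 kept it with the same sign. In 12 the relation did not pass, and in 1 it passed with the opposite sign, as the stress share turned to r = -0.483 (rho = -0.578, adjusted permutation p = 0.0013), for which the cause was not tested. A candidate explanation is that shares of categories with weakly hybridising probes depend on how many probes pass detection. The test cannot single it out, because a change in genes not always detected could also be lost over probes detected on every array. Of those probes, bacteriophage had only 6, the other category 13 and energy process 15.

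The 20 counts of families and probes past adjusted p 0.05 were all at 0. All 100 assignments of the treatments, the real one among them, therefore had to give as many. The comparison says nothing about chance. Reassignments for heat and CO2 crossed replicate numbers. Between 0 and 6 of the 100 called any family or probe, by treatment or pair. The highest numbers of families in the other reassignments were 16 for nitrogen, 6 for water and 256 for CO2, and for heat 22.7% of the 497. For the pairs they were 55 for nitrogen with water, 0 for nitrogen with heat, 2 for nitrogen with CO2, 2 for water with heat, 81 for water with CO2 and 5 for heat with CO2. For probes they were 2016 for nitrogen, 213 for water, 2465 for CO2 and for heat 0.616% of the 20606, and 3, 418, 1459, 22, 142 and 537 for the pairs in the same order. Such large numbers came from few reassignments, and whether they follow a structure of the samples was not tested.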
